A study of Mus musculus with 6 samples.

How the data were processed

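RNA of sorted GFP-positive cells was measured in 6 samples, 3 of calvarial osteoblasts and 3 of molar cementoblasts. Per the labels, tissue was digested with trypsin and collagenase, the calvarial digest after a discarded first fraction, cells were sorted, and RNA was amplified and biotinylated. The deposited table of non-normalized values holds the bead signal as an intensity on a linear scale for 25697 probes, and per the file headers a detection p-value beside each. These p-values move in steps set by 798 negative control types. The second deposited table holds intensity values that the submitters normalized; lumi is named in the submitters' processing notes, its version and method are not given in the sources used here, and image processing is not given either. Compared column by column, those values are on the same linear scale and keep each array's rank order, and the column of osteoblast replicate 2 equals its non-normalized values at all 25697 probes. The direction of the values is not in doubt, and no centring was seen: the medians of the normalized columns ran from 95.6 to 98.2. In the non-normalized table they were 81.2, 95.6 and 111.1 for the osteoblast arrays and 82.7, 78.5 and 81.7 for the cementoblast arrays. A column was matched to its sample by title; for replicate 3 of each group the column carries the tissue code and the replicate number of the description, where the title has another number.

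Background was corrected with neqc of limma 3.58.1 in R 4.3.3, which fits the background from the detection p-values, adds an offset of 16, normalizes by quantiles and takes log2. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept, which left 11198. Gene symbols came from the platform annotation: 23978 probes had a single symbol, 1719 had none here and none had several. The brightest kept probe by mean over all arrays stood for a gene, which gave 8111 genes; 1893 of them had other kept probes, and disagreement is stated where such a gene is named. The number of arrays limits the precision, and signals near 4 on the log2 scale lie at background, so no fold is given for a gene not detected on all arrays of both groups except as a bound, and a log2 difference of such a gene is taken against background. For a gene below detection on all arrays of a group, the fold is given as "at least", from the mean of the other group over the mean, per array, of the higher of the lowest detected signal and the gene's own. That lowest detected signal was 5.11, 4.37 and 4.40 on osteoblast replicates 1, 2 and 3. It was 4.80, 4.75 and 4.75 on cementoblast replicates 1, 2 and 3, so the edge of detection differed between arrays.

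Differences are cementoblast minus osteoblast, fitted with lmFit and eBayes, with Benjamini-Hochberg adjustment over all genes at 0.05. The labels number replicates 1 to 3 in both groups without saying that a number marks shared animals or days, so no block was used. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 39 lists with at least 5 genes tested out of 44 set up, and again with an estimated correlation and with fry. The test, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names the 12 genes with the largest change in each direction among those past the test whose groups do not overlap, 21 genes of mineralised tissue and Wnt or BMP signalling, and for each list up to 4 members past the test or else the member with the smallest p. Values of list members with the smallest p are printed where a list or group is described. On simulated arrays with the means and spreads of the 8111 genes and 200 changed genes (20 data sets), the test called 11.3% of genes changed by 1 on the log2 scale, 85.7% of those changed by 2 and 97.6% of those changed by 3, with 0.091% of the unchanged genes called. Camera called all 20 simulated lists of 15 genes shifted by 1, and 1 of 20 unshifted lists at an unadjusted p under 0.05; the simulated genes were independent of each other.

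The alternatives were the submitters' values, no background correction, scaling to the 75th percentile, other filters and probe choices, trend and robust variance, array weights, the replicate number or title number as a block, a fold threshold of 1.5 inside the test, and leaving out each array. Covariates for neutrophil markers and for brightness, and cementoblast replicate 3 alone against the osteoblasts, were added after seeing the data.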

Results

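Gene expression was measured on Illumina bead arrays in sorted cells of adult C57Bl6/J mice that carry OC-GFP, a fluorescent reporter of osteocalcin expression and so of cells that form mineralised matrix. The GFP-positive cells came either from the calvaria, the flat bones of the skull (osteoblasts), or from the surface of extracted molars (cementoblasts, the cells that lay down the mineral layer on the tooth root). Each group held 3 samples. Every osteoblast sample pooled 6 mice, and the cementoblast samples pooled 7, 10 and 6 mice. The labels do not say whether the same mice gave both tissues, and the spread between samples is that between pools of mice of both sexes aged 5 to 7 weeks.

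The arrays differed in brightness within the groups. Osteoblast replicates 1, 2 and 3 detected 8480, 13347 and 12922 of 25697 probes, and cementoblast replicates 1, 2 and 3 detected 9791, 10059 and 10040. Correlations of log2 signal between arrays of one group ran from 0.807 to 0.962, and those between groups from 0.804 to 0.911. The first principal component held 49.0% of the variance and did not part the groups: osteoblast replicate 1 and cementoblast replicate 3 lay together at its low end, at -40.8 and -37.5, and cementoblast replicates 1 and 2 at its high end, at 44.1 and 34.7. The second component, with 20.9% of the variance, had all 3 osteoblast arrays above 0 and all 3 cementoblast arrays below it.

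**Figure D1:**
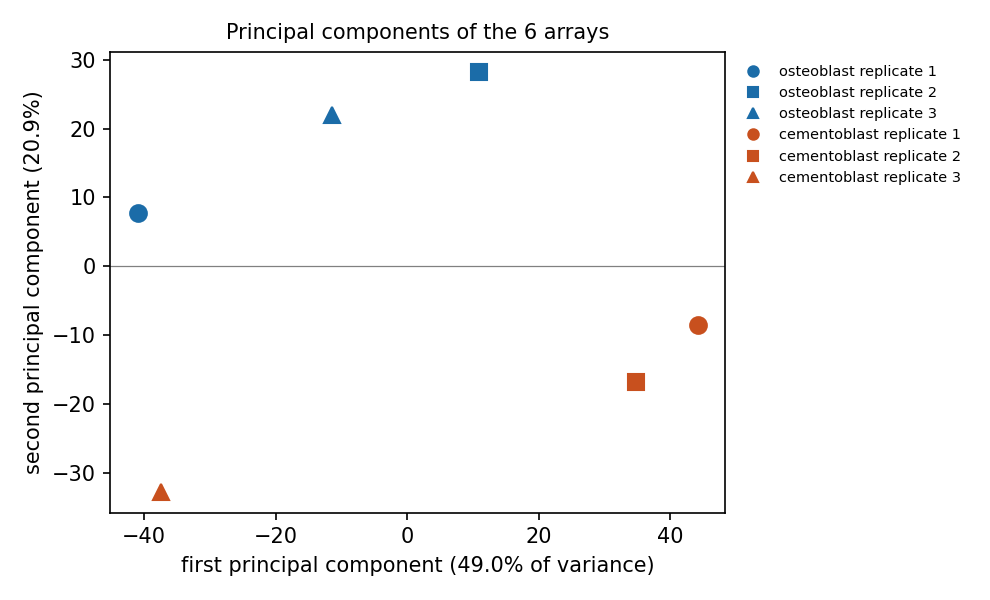
Scores of the 6 arrays on the first component (horizontal axis, 49.0% of variance) and the second (vertical axis, 20.9%), in units of log2 signal over 8111 genes, with colour for the group and symbol for the replicate. The groups part on the vertical axis, while osteoblast replicate 1 and cementoblast replicate 3 share the left side at -40.8 and -37.5.

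The comparison of the groups asked which genes set cementoblasts of the molar apart from osteoblasts of the skull. Genes past the test in both directions included transcription factors that pattern the head. Osr2, an odd-skipped factor of the palate and tooth, had a log2 signal of 9.73 ± 0.51 (SD, n = 3) in cementoblasts against 5.00 ± 1.15 (SD, n = 3) in osteoblasts, where 2 of 3 arrays detected it (limma adjusted p = 0.0246). Barx1, a homeobox factor of molar-forming mesenchyme, was higher in cementoblasts, at 8.26 ± 0.41 against 4.35 ± 0.07 (SD, n = 3 each; limma adjusted p = 0.00661), and 1 of 3 osteoblast arrays detected it. Zic1, a zinc-finger factor of the skull, was lower, at 4.41 ± 0.34 against 7.82 ± 0.14 (SD, n = 3 each; limma adjusted p = 0.00661), and 1 of 3 cementoblast arrays detected it. The genes for bone collagen and for osteocalcin did not pass the test.

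Of 8111 genes tested, 12 were higher and 14 lower in cementoblasts at an adjusted p under 0.05. All 26 differed by at least 2-fold, and in all 26 the 3 arrays of one group lay above the 3 of the other. Such separation occurred in 916 genes, or 11.3%, where chance gives 10%. At an unadjusted p under 0.05, 282 genes were higher and 279 lower. The limma counts changed when a single array was left out, which also leaves fewer samples to test. With osteoblast replicate 1, 2 or 3 left out they were 5 higher and 10 lower, 2 and 1, and 3 and 1. With cementoblast replicate 1, 2 or 3 left out they were 9 and 1, 0 and 0 (394 at an unadjusted p under 0.05), and 105 and 61. Scaling each array to its 75th percentile left 0 higher and 2 lower (599 at an unadjusted p under 0.05), and the values as the submitters normalized them gave 5 and 9; all 26 genes had the same direction under both scalings. With the replicate number as a block the counts were 0 and 0 (568 at an unadjusted p under 0.05), and with the number in the titles, which replicates 2 and 3 share across the groups, as a random block they were 38 and 36.

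The other genes higher in cementoblasts were led by Foxq1, a forkhead factor, with a log2 difference of 4.43 (SE 0.43, n = 3 per group; adjusted p = 0.0132). Dlx1, a distal-less homeobox factor of the jaw, differed by 3.47 (SE 0.38; adjusted p = 0.0168), and Tbx3, a T-box factor, by 2.94 (SE 0.27; adjusted p = 0.0114); another probe of Tbx3 differed by 1.81 and did not pass. Twist2, a basic helix-loop-helix factor, differed by 2.77 and Bcl11a, a zinc-finger factor, by 1.87. Outside the transcription factors, the thrombin receptor gene F2r differed by 3.18 and was detected on all 6 arrays, at 10.26 ± 0.21 in cementoblasts against 7.08 ± 0.58 (SD, n = 3 each). Aox3, an aldehyde oxidase, was below detection on every osteoblast array and was at least 6.96-fold higher in cementoblasts. 6330403K07Rik, Tcim and Mustn1 differed by 2.75, 2.67 and 2.20, and another probe of Mustn1 differed by 0.91 and did not pass. The adjusted p of these 12 genes ran from 0.00661 to 0.0354. Foxq1, Dlx1 and Bcl11a were detected on 1 osteoblast array and Tbx3, Twist2, 6330403K07Rik, Tcim and Mustn1 on 2, so their log2 differences are taken against signals near background.

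The genes lower in cementoblasts held matrix proteins, signalling molecules and ion channel genes beside transcription factors. Fmod, which encodes the collagen-binding fibromodulin, fell by 3.85 on the log2 scale (SE 0.51, n = 3 per group; adjusted p = 0.0304), and Comp, a cartilage matrix protein, fell by 2.77 (SE 0.32; adjusted p = 0.0215). Angpt2, a ligand of the endothelial receptor Tie2, was at 6.26 ± 0.48 in cementoblasts against 9.26 ± 0.25 (SD, n = 3 each; adjusted p = 0.0157). Efna5, an ephrin ligand, was at 7.95 ± 0.21 against 10.15 ± 0.35 and Dner at 6.33 ± 0.24 against 9.02 ± 0.57 (SD, n = 3 each). Meis2, a homeobox factor, had a log2 difference of -2.70, Ranbp3l of -3.75 and the potassium channel gene Kcnk2 of -1.96; Meis2, Ranbp3l and Comp were detected on 1 cementoblast array and Kcnk2 on 2. Other probes of Efna5 and Ranbp3l did not pass, at -0.41 and -0.02, with mean signals of 4.76 and 4.72. En1, a homeobox factor, Kcnab1, a potassium channel subunit, and Galnt9, a glycosyltransferase, were below detection on every cementoblast array and at least 2.92-fold, 4.34-fold and 3.26-fold lower there; another probe of Kcnab1 did not pass, at -1.41. Caln1, at least 2.96-fold lower, and the lipase gene Mgll, with a difference of -1.72 (other probes, at -1.71 and -2.04, did not pass), completed the 14 and are named although they fell outside the naming rule.

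**Figure D2:**
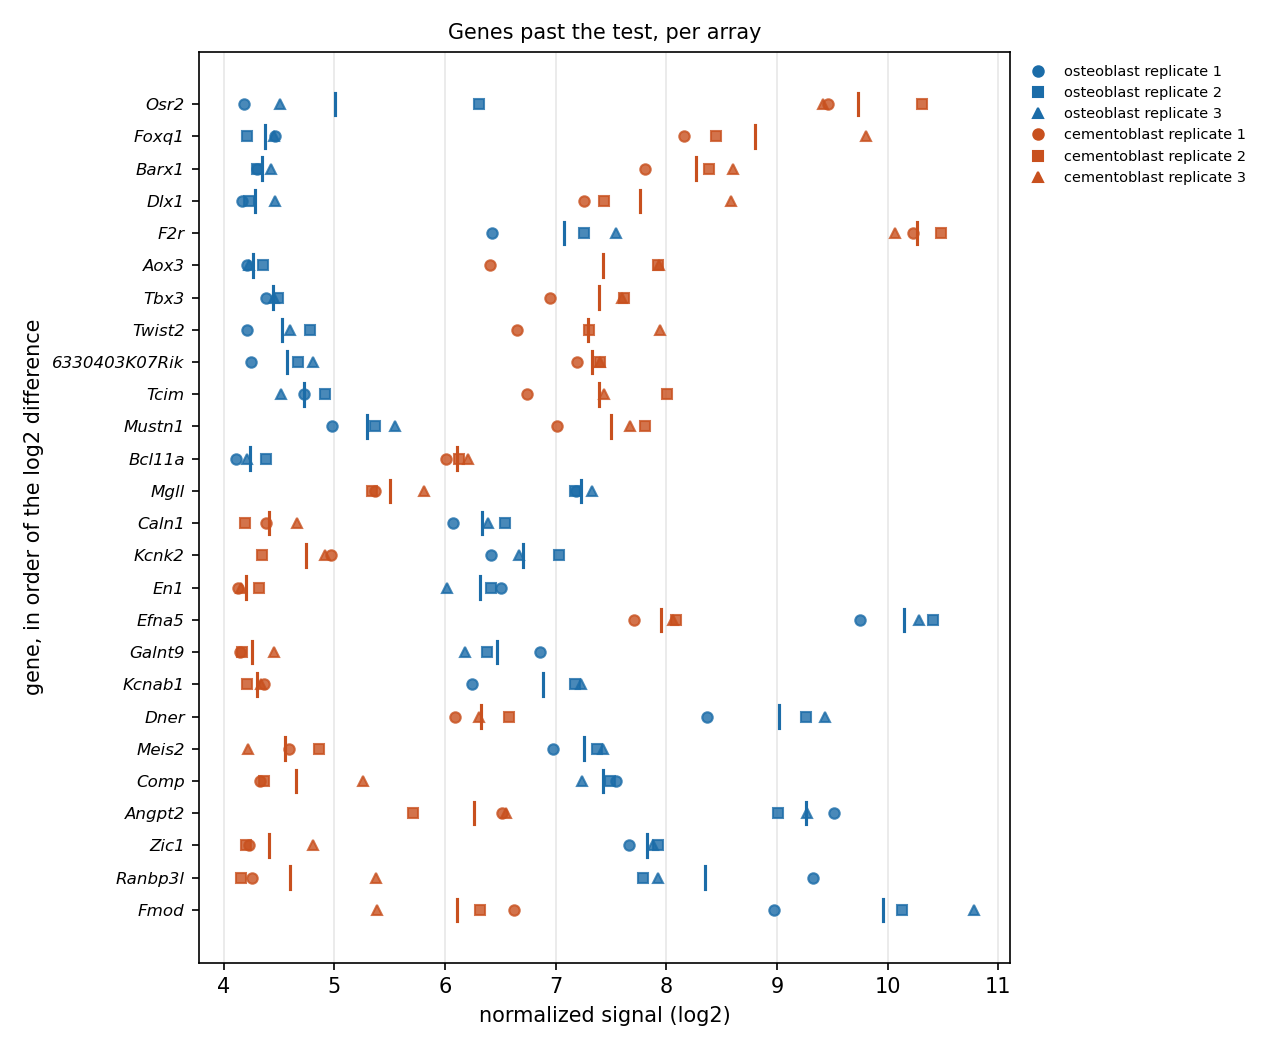
Normalized log2 signal (horizontal axis) of the 26 genes past the test, in order of the log2 difference between groups, with a symbol for each array and a bar at each group mean (n = 3). In all 26 genes the groups do not overlap, from Osr2 (9.73 against 5.00) at the top to Fmod (6.11 against 9.96) at the bottom.

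Of the 10 tested members of the jaw and tooth patterning list, 3 were higher in cementoblasts (Osr2, Barx1 and Dlx1) and none was lower. The median difference was 1.09 on the log2 scale, with 9 of 10 members above 0 (camera adjusted p = 1.4e-08 with its preset correlation, adjusted p = 0.313 with an estimated correlation, and adjusted p = 0.033 by fry). The member below 0 was Dlx5, detected on all osteoblast arrays and on no cementoblast array. It stood at 4.45 in cementoblasts against 5.10 in osteoblasts, close to the edge of detection, and was named after its values were seen. Adjusted over the list alone, 5 members were higher, the further ones being Dlx2, below detection on every osteoblast array and at least 2.01-fold higher in cementoblasts, and Lhx8, at 6.13 against 4.29 and detected on 1 osteoblast array, both named after their values were seen. The median was smaller with the submitters' values (0.65), with no background correction (0.38) and with no filter on detection (0.17), and the call held in all 3. In the calvarial patterning list, Zic1 and En1 were lower and Twist2 was higher among 10 members tested. That list had a median of -0.36 (camera adjusted p = 0.0118, and adjusted p = 0.787 with an estimated correlation). Adjusted over the list alone, 3 were lower, with Prrx1 (-1.42) as the further one, and 1 higher. The calvarial call was lost without cementoblast replicate 1 (median -0.11, adjusted p = 0.0781), with the number of detected probes as covariate at an unchanged median of -0.36 (0.0905) and by fry (0.1). Its median was -0.04 with the neutrophil covariate and -0.66 without cementoblast replicate 3. Mean log2 signals of its members were 6.17, 6.37 and 6.78 on cementoblast replicates 1, 2 and 3 and 6.81 to 7.07 in osteoblasts, and cementoblast replicate 3 set alone against the osteoblasts gave a median of 0.17. The jaw call kept its side of the threshold with each of the 6 arrays left out in turn.

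The genes of mineralised matrix by which both cell types are known showed no single-gene call. Col1a1, the gene for the main bone collagen, was at 13.95 ± 0.05 in cementoblasts and 13.97 ± 0.10 in osteoblasts (SD, n = 3 each), a difference of -0.02 with a 95% interval from -0.53 to 0.49. On every array it stood near the highest normalized signal, 14.21, where quantile normalization leaves little room for a difference. Bglap and Bglap2, near-identical osteocalcin genes whose probes may not tell them apart, differed by -0.78 and -0.71, and other Bglap probes by -1.13 and -2.72. On osteoblast replicates 1 and 2 and cementoblast replicate 3, Bglap2 stood at that highest signal and Bglap at 14.07, so their differences are not measured above it. Both groups were also sorted on a reporter of osteocalcin expression, so the levels of these genes are not independent of the sort. Alpl (-0.28), Sp7 (-0.75) and Ibsp (1.02, and 2.15 at another probe) did not pass either. Of the genes typical of embedded osteocytes, Dmp1 differed by 0.87, Mepe by 0.11 and Phex by 0.11, none past the test and none detected on all 6 arrays. Sost, Dspp and Postn were below detection on all 6 arrays, Dkk1 and Tnfsf11 were detected on 2, and Spp1 and Runx2 were not analysed here.

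Of the 19 tested genes of bone matrix and osteoblast differentiation, 14 lay below 0, with a median of -0.52 (camera adjusted p = 0.0208, and adjusted p = 0.884 with an estimated correlation). Adjusted over the list alone, 1 was lower: Pth1r, the parathyroid hormone receptor, with a difference of -2.59 (adjusted p = 0.096 over all genes; its other 2 probes, at -2.80 and -2.57, had adjusted p = 0.0239 and 0.0255 over all probes). The list call was lost without osteoblast replicate 1 (median -0.34, adjusted p = 0.181), cementoblast replicate 1 (-0.20, 0.211) or cementoblast replicate 2 (-0.23, 0.131), with the neutrophil covariate (-0.30, 0.303) and by fry (0.776). Without cementoblast replicate 3 the median was -0.83, and that array had a list mean of 10.05, against 8.98 on both other cementoblast arrays and 9.52 to 10.19 in osteoblasts. Set alone against the osteoblasts, that array gave a median of 0.18. Of 22 small leucine-rich proteoglycan and matricellular genes, Fmod and Comp were lower, 16 lay below 0 and the median was -0.29 (camera adjusted p = 0.0118, and adjusted p = 0.794 with an estimated correlation). Adjusted over the list alone, 4 were lower and 1 higher; this call was lost at a smaller median without osteoblast replicate 3 (-0.06, adjusted p = 0.0596), with no filter on detection (-0.14, 0.167) and with the number of detected probes as covariate (-0.15, 0.126), at a larger one without cementoblast replicate 3 (-0.39, 0.276), and by fry (0.423). It held without osteoblast replicate 1 and without cementoblast replicate 2, at medians of -0.54 and -0.48. Of 15 periodontal ligament and tendon genes, Fmod alone was lower over all genes, 3 were lower and 1 higher adjusted over the list alone, and the list did not pass (adjusted p = 0.223).

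Among signalling lists, the Wnt antagonists and the Notch list lay higher in cementoblasts without any gene past the test over all genes. Of 11 Wnt antagonists, 9 lay above 0, with a median of 0.47 (camera adjusted p = 0.00583, and adjusted p = 0.313 with an estimated correlation). Wif1, a secreted Wnt inhibitor, was 5.66-fold higher, at 10.99 ± 0.77 against 8.49 ± 0.48 (SD, n = 3 each; limma adjusted p = 0.0858), and Sfrp1, detected on 2 osteoblast arrays, differed by 2.10 (adjusted p = 0.313). These 2 passed when adjusted over the list alone. The Wnt antagonist call was lost with no filter on detection, where the median was 0.06 (adjusted p = 0.211), and by fry (0.1), and the median was 0.75, 0.71 and 0.85 without osteoblast replicate 1, osteoblast replicate 2 and cementoblast replicate 1. It was 0.93 under 75th percentile scaling, 0.81 with the number of detected probes as covariate and 0.29 with no background correction. Of 10 Notch pathway genes, 9 lay above 0, with a median of 0.54 (camera adjusted p = 0.00612, and adjusted p = 0.696 with an estimated correlation). Only Dlk1, a Notch ligand homologue, passed adjusted over the list alone; it stood at 7.93, 8.63 and 5.69 on cementoblast replicates 1, 2 and 3 and was detected on 1 osteoblast array. The Notch call was lost without cementoblast replicate 1 (median 0.46, adjusted p = 0.0571) or 2 (0.26, 0.06), the arrays with bright epithelial keratins, with the number of detected probes as covariate (0.42, 0.0588) and by fry (0.561). Mean Notch list signals were 6.52 and 6.70 there, 5.60 on cementoblast replicate 3 and 5.46 to 5.64 in osteoblasts, and replicate 3 set alone against the osteoblasts gave a median of -0.05. Tnfrsf11b, the osteoprotegerin gene, differed by 1.40, Bmp4 by 1.24 and Bmp3 by -0.81, none past the test.

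All 25 cytosolic ribosomal protein genes tested lay above 0, with a median of 0.24, but their median was -0.02 under scaling to the 75th percentile, where the median of all genes was -0.08. The list passed (camera adjusted p = 0.000472, and adjusted p = 0.627 with an estimated correlation) and no gene of it did; by fry it did not pass (adjusted p = 0.1), and without osteoblast replicate 2 the median was 0.15. The hypoxia and glycolysis list had 14 of 18 genes above 0 and a median of 0.40, or 0.01 under 75th percentile scaling (camera adjusted p = 0.0186, and adjusted p = 0.813 with an estimated correlation). No member passed over all genes or adjusted over the list alone, and the call was lost without osteoblast replicate 1 (median 0.35, adjusted p = 0.085), cementoblast replicate 1 (0.33, 0.0598) or cementoblast replicate 2 (0.33, 0.191), with the neutrophil covariate (0.25, 0.148) and by fry (0.561). Cementoblast replicate 3 set alone against the osteoblasts gave a median of 0.02.

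Markers of other cell types differed between arrays of the same group. Keratins of the oral epithelium were bright on cementoblast replicates 1 and 2 and at background elsewhere: Krt14 had log2 signals of 11.57 and 11.18 there, 4.47 on cementoblast replicate 3 and 4.17 to 4.49 in osteoblasts. Of 20 epithelial markers on the array, 14, 12 and 2 were detected on cementoblast replicates 1, 2 and 3, and 1, 4 and 2 on the osteoblast arrays. Only 4 epithelial genes entered the test and none passed over all genes; Ambn, the enamel matrix gene ameloblastin, differed by 3.01 (adjusted p = 0.182), and Ambn and Krt14 passed adjusted over the list alone. The 15 neutrophil genes all lay above 0 with a median of 0.94 (camera adjusted p = 0.00612, and adjusted p = 0.884 with an estimated correlation), none past the test over all genes or over the list alone. Their mean log2 signals were 6.08, 9.05 and 8.58 on osteoblast replicates 1, 2 and 3, and 10.69, 9.09 and 7.13 on the cementoblast arrays, and the call was lost without osteoblast replicate 1 (median 0.23, adjusted p = 0.707) or cementoblast replicate 1 (0.10, 0.705) and by fry (0.876). The neutrophil median was 1.58 without osteoblast replicate 2, 2.17 without cementoblast replicate 3 and 1.86 with the number of detected probes as covariate. The 14 endothelial genes also lay above 0, with a median of 0.92 and none past the test (camera adjusted p = 0.00516, and adjusted p = 0.884 with an estimated correlation). Of 15 endothelial genes on the array, 13, 13 and 1 were detected on cementoblast replicates 1, 2 and 3, and the call was lost without osteoblast replicate 1 (median 0.52, adjusted p = 0.117), cementoblast replicate 1 (0.36, 0.227) or cementoblast replicate 2 (0.49, 0.191), with the neutrophil covariate (0.28, 0.197) and by fry (0.803). The endothelial median was 1.87 without cementoblast replicate 3, 0.55 with the submitters' values and 0.38 with no background correction. Mean endothelial signals were 4.59, 5.06 and 5.73 on osteoblast replicates 1, 2 and 3, and 6.73, 6.66 and 4.35 on the cementoblast arrays. Against the osteoblasts, cementoblast replicate 3 alone had medians of -0.68 for the neutrophil list and -0.998 for the endothelial list. All 6 skeletal muscle genes tested lay below 0 in cementoblasts, with a median of -0.86 (camera adjusted p = 2.63e-05, adjusted p = 0.302 with an estimated correlation, and adjusted p = 0.033 by fry), or -0.24 with no background correction. None passed over all genes, and Actn3, Myl1 and Mb were lower adjusted over the list alone.

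**Figure D3:**
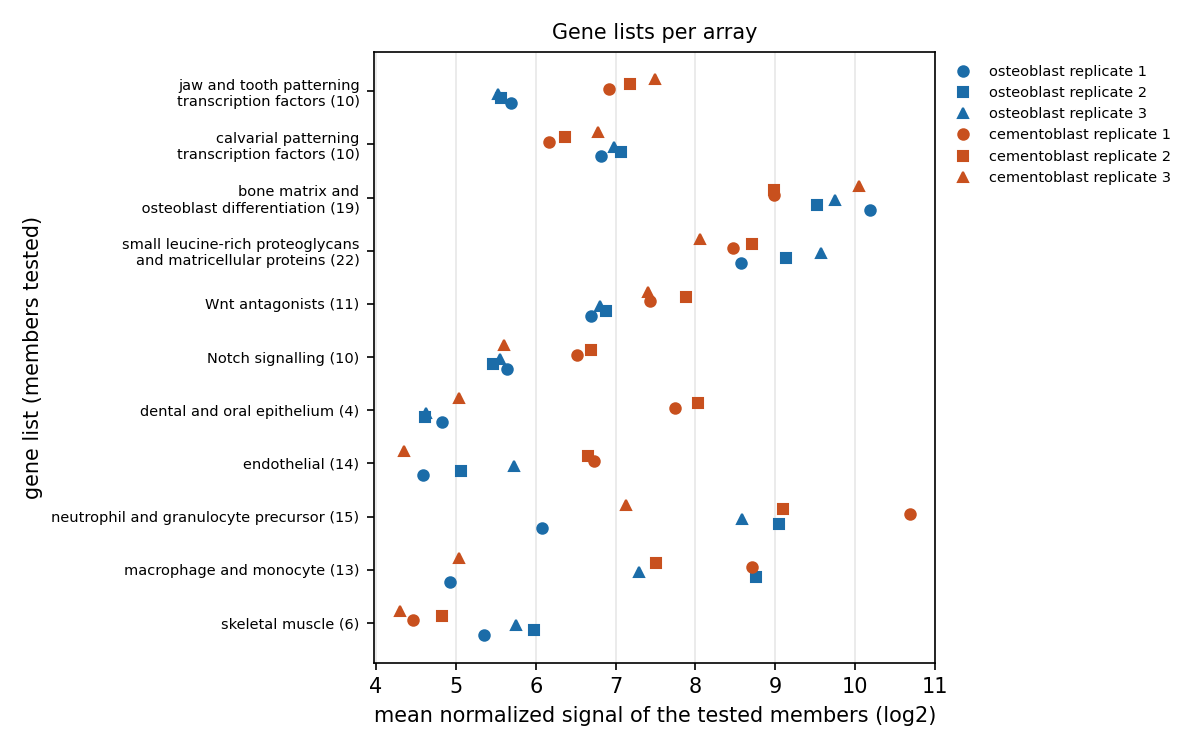
Mean normalized log2 signal of the tested members (horizontal axis) of 11 gene lists, with the number of members in brackets and a symbol for each of the 6 arrays. The jaw list lies between 6.92 and 7.49 on the cementoblast arrays and between 5.52 and 5.69 on the osteoblast arrays, while the epithelial, endothelial and neutrophil lists are lower on cementoblast replicate 3 than on replicates 1 and 2.

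The other 28 lists tested did not pass with camera. The closest were the TGF-beta list (17 genes, median 0.18, or -0.18 under 75th percentile scaling, adjusted p = 0.0583) and the secretory pathway list (21 genes, median -0.26, adjusted p = 0.0874), neither with a gene past the test over all genes; Ltbp4 and Inhbb were higher adjusted over the TGF-beta list alone, where the Ltbp4 probe used differed by 1.84 and others by 1.90 and 0.46. Adjusted p was 0.107 for cell cycle, 0.193 for FGF signalling, 0.228 for axon guidance (Efna5 lower), 0.234 for both the IGF system and the matrix proteases, 0.337 for collagens and 0.427 for mineralisation genes. Among the collagens, Col18a1, Col7a1 and Col2a1 were higher and Col8a2 lower adjusted over the list alone, with Col18a1, detected on 2 osteoblast arrays, closest over all genes (2.90, adjusted p = 0.057). Adjusted p was 0.584 for osteocyte genes, canonical Wnt targets, the dissociation stress genes and T and NK cell markers, 0.581 for odontoblast markers, 0.663 for osteoclast and for Schwann cell and neuron markers, and 0.667 for oxidative phosphorylation. It was 0.831 for BMP antagonists and targets, macrophage markers and stromal progenitor markers, 0.885 for pericytes, 0.896 for Wnt ligands and receptors, BMP ligands, B lineage and chondrocyte markers (Comp lower), 0.914 for interferon genes and 0.922 for osteoclast support. Adjusted over the list alone, Capg, Wnt10a, Col2a1 and Col9a2 were higher in the osteocyte, Wnt ligand and chondrocyte lists; the Capg probe used differed by 1.57 and another by 0.54. Vdr, Rspo3, Gdf10, Nog, Bmper, Fap, Pth1r and Thy1 were lower in theirs. Median and mean differed in sign for the Wnt ligand, BMP antagonist, oxidative phosphorylation, T and NK cell, pericyte, chondrocyte and stromal lists. Hedgehog, erythroid, adipocyte and sex-linked genes, with 1, 4, 4 and 3 genes tested, were too few for the list test, and none of them passed alone.

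Of 16593 genes with a named probe, 5006 were detected on all 6 arrays, 25 on all cementoblast and no osteoblast arrays, and 90 the other way. No test was run on these counts, and the brighter osteoblast replicates 2 and 3 detected more probes than any cementoblast array. Of the genes past the test, Aox3 was among the 25, and Kcnab1, Galnt9, En1 and Caln1 were among the 90.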

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

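The neutrophil covariate, the detected-probe covariate and cementoblast replicate 3 set alone against the osteoblasts were chosen after seeing the data; the other alternatives were planned. All 26 genes past the test kept their direction in all 21 settings of the gene test; because their groups do not overlap, leaving out an array or setting cementoblast replicate 3 alone against the osteoblasts could not turn it, so this says little. Their calls did not all hold: of 546 values, 285 were past the threshold and 261 were not. Of 9 other probes of these genes, 2 were past it. Barx1 was past it in 18 of 21 settings and Zic1 in 17. The median standard error was 0.311 on the log2 scale, signals near background allow no exact fold, and the cause of the changes in counts was not tested except where the construction shows it.

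Genes higher in cementoblasts numbered 12 and genes lower in cementoblasts 14 as reported. The counts were 5 and 9 with the submitters' normalized values, 5 and 10 with no background correction (5 and 9 at least 2-fold), and 0 and 2 with 75th percentile scaling (limma; 599 at an unadjusted p under 0.05). They were 4 and 4 with no filter on detection, where 16593 genes were tested, and 20 and 18 with probes detected on all arrays of one group, where 6437 were. They were 17 and 23 with trend and robust variance, 111 and 88 with array weights (110 and 87 at least 2-fold), and 7 and 3 with treat at a fold of 1.5, a stricter test by construction. Array weights gave cementoblast replicate 3 the lowest weight, 0.309. Deviations from the group mean correlated across genes at -0.356, 0.362 and 0.0901 between arrays of replicate number 1, 2 and 3, and genes are not independent replicates. Replicates 2 and 3 also share a number in their titles across the groups and have the same age range, and replicates 1 share neither, so a shared day or shared animals for replicates 2 or 3 cannot be ruled out. The replicate block left 0 and 0 in limma (568 at an unadjusted p under 0.05), and the title number as a random replicate block gave 38 and 36 at a consensus correlation of 0.35. With the neutrophil marker level as covariate the counts were 25 and 31, with the number of detected probes 6 and 8, and with cementoblast replicate 3 alone 6 and 1; in the last fit the lone array is assumed to vary like the osteoblasts. Leaving out each array in turn gave 0 to 105 higher and 0 to 61 lower, with 0 and 0 without cementoblast replicate 2 (394 at an unadjusted p under 0.05) and 105 and 61 without cementoblast replicate 3. Of the 26 genes, 11 were still past the test with the submitters' values, 2 with 75th percentile scaling and 26 without cementoblast replicate 3.

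The gene lists that differ numbered 11. With the correlation estimated for each list there were 0 (lowest adjusted p 0.302), with fry 2, and with cementoblast replicate 3 alone 19, of which 7 were shared with the 11. Leaving out each array gave 6 to 16, with 6 without cementoblast replicate 1, 5 of them shared, and 7 without cementoblast replicate 2, all shared. The other list settings gave 11 to 13. The jaw list's adjusted p ran from 3.08e-10 with the neutrophil covariate to 0.313 with an estimated correlation, with a positive median in each list setting. With cementoblast replicate 3 alone the list medians reversed for bone matrix (0.18), Notch (-0.0486), neutrophils (-0.68) and endothelium (-0.998). The calvarial patterning median reversed as well (0.17), with the test still pointing down. For hypoxia the median shrank to 0.0213 and stayed above 0, with the test pointing down. The neutrophil list with its own level as covariate had a median of -0.11 (adjusted p = 0.877), by construction. Of the other list values, 114 for called lists stayed past the threshold and 44 did not, and 39 for lists not called became past it. With the submitters' values, no background correction and 75th percentile scaling, in that order, the list medians were -0.37, -0.27 and -0.73 for bone matrix, 0.35, 0.29 and 0.93 for Wnt antagonists, 0.33, 0.21 and 0.77 for Notch, 0.65, 0.38 and 1.31 for the jaw list, -0.37, -0.21 and -0.79 for the calvarial list, -0.18, -0.17 and -0.54 for proteoglycans, 0.29, 0.22 and 0.01 for hypoxia, 0.37, 0.22 and -0.02 for ribosomal proteins, 0.89, 0.76 and 0.47 for neutrophils, 0.55, 0.38 and 0.63 for endothelium and -0.47, -0.24 and -0.39 for skeletal muscle.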

Other observations

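The tests of the patterns below were chosen after the results were seen; the counts over other splits of the arrays were planned.

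Some genes of mineralising cells were brighter on cementoblast replicate 3 than on the other cementoblast arrays; Col1a1 was not, at 13.90 against 13.98 on both. Ibsp, which encodes bone sialoprotein, had a log2 signal of 13.23 on that array, against 11.20 and 10.15 on cementoblast replicates 1 and 2 and 10.53, 10.00 and 11.003 in osteoblasts. Dmp1, a matrix protein of osteocytes, stood at 7.11, against 4.38 and 5.57 on these arrays and 5.56, 4.52 and 4.37 in osteoblasts. Phex, a regulator of phosphate handling, stood at 8.14, against 6.26 and 4.38, with 6.32, 5.15 and 6.99 in osteoblasts. Bmp3 stood at 10.16, against 6.82 and 6.91, with 9.39, 8.01 and 8.94 in osteoblasts. These genes were picked after their values were seen, and a single array gives no test.

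On cementoblast replicates 1 and 2, and on no other array, 121 genes were detected. The brightest was Krt13, a keratin of stratified oral epithelium, with a mean log2 signal of 10.84, followed by Krt5 at 9.53 and Krt15 at 8.82. Among genes detected in osteoblasts alone, Esm1, an endothelial proteoglycan, stood at 7.28 against 4.32 in cementoblasts, and Cilp2, a cartilage protein, at 7.09 against 4.30. Wnt10a, a Wnt ligand of the tooth, stood at 6.58 in cementoblasts against 4.27.

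The first pattern is the higher level of jaw patterning factors in cementoblasts. Oral epithelium in the sort is argued against for cementoblast replicate 3, where the 10 members had a median difference of 1.49 from the osteoblasts (quartiles 0.605 and 3.81, 9 of 10 above 0) and 4 keratins one of 0.00175; for replicates 1 and 2, with medians of 0.89 and 4.96, the tables leave it open. Array brightness is argued against by the camera adjusted p of 6.89e-05 with the number of detected probes as covariate. Over the list's alternatives the adjusted p ran from 3.08e-10 to 0.313. The camera call held with each of the 6 arrays left out in turn (highest adjusted p = 4.37e-05). The list's array means did not overlap between the groups, so this holding cannot decide on a single mislabelled array. The tissue of origin, jaw against skull, remains an open explanation and was not tested. As to chance, 10 splits of the 6 arrays are too few for a share under 0.05. The real split gave 26 genes past the limma test and the highest other 0. At an unadjusted limma p under 0.05 it gave 561 and the highest other 1576, for osteoblast replicates 1 and 3 with cementoblast replicate 3. For gene lists it gave 11 and the highest other 13, and 5 of the 10 splits, the real one included, gave as many.

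The second pattern is the bright keratins on cementoblast replicates 1 and 2 but not 3. A dimmer array for replicate 3 is argued against by its 10040 detected probes, between the 9791 and 10059 of the other arrays. Oral epithelial cells in those sorts may be the source: of 16 other epithelial genes on the array, 5 (31.3%; Cdh1, Dsg3, Lgals7, Sfn and Trp63) were detected on those arrays alone, against 0.682% of 16573 other genes (one-sided Fisher's exact p = 6.86e-08). Genes are not independent replicates and the arrays were picked after their keratins were seen, so this p does not speak for other sorts. Of the 20 genes of the list, 1 is also in another list. A sort for OC-GFP would remove epithelial cells unless they carried the signal or stuck to positive cells. No biological explanation for a difference within the group was tested.

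The third pattern is the first principal component, which did not follow the groups and put osteoblast replicate 1 with cementoblast replicate 3. Differing amounts of leukocyte RNA are a candidate explanation. Computed without 117 marker genes of cell types, the component still followed the neutrophil level over the 6 arrays. Pearson r was 0.923 (exact permutation p = 0.00417, adjusted p = 0.00833). Spearman rho was 1 (exact permutation p = 0.00278, the smallest 6 arrays can give, adjusted p = 0.00556). The adjustment covered 2 relations, and r was 0.884 without osteoblast replicate 1 and cementoblast replicate 1. The neutrophil list was picked after its array means were seen, so these p-values do not measure that choice. Cell cycle and endothelial means were also lowest on osteoblast replicate 1 and cementoblast replicate 3, and highest on cementoblast replicates 1 and 2. Cell cycle stood at 5.03 and 4.82 on the former, and 6.47 and 5.82 on the latter, with 5.80 on osteoblast replicate 2. Not all lists had this order. Macrophage means were 4.92, 8.75 and 7.30 on osteoblast replicates 1, 2 and 3, and 8.71, 7.51 and 5.04 on the cementoblast arrays. They were lowest on the same arrays but highest on osteoblast replicate 2. The relation of the component to the neutrophil level does not single out leukocyte RNA. The neutrophil gene S100a8 ranged from 8.80 to 12.42 in osteoblasts and from 11.35 to 14.21, the highest signal on the array, in cementoblasts. Of the 16 neutrophil genes, 2 are also in another list. A sort for GFP would remove leukocytes unless they carried the signal or stuck to positive cells, and neutrophil marker signal was present after it. Brightness as the number of detected probes is argued against among the cementoblasts, where replicates 2 and 3 differed by 19 probes and lay 69.5 apart. Their non-normalized signals were less alike, with 75th percentiles of 85.8 and 94.9 and highest signals of 7843 and 17325. Brightness by signal therefore stays open there. It also stays open among the osteoblasts, where the dimmest array, replicate 1, lay lowest at -37.9. Over all 6 arrays the number of detected probes had r = 0.165 with the component (exact permutation p = 0.724) and rho = 0.257 (exact permutation p = 0.658). A swap of osteoblast replicate 1 and cementoblast replicate 3 is argued against by the jaw-minus-calvarial list level, with 6 of 6 arrays on their group's side (-1.13 and 0.72 for these arrays; osteoblasts -1.36 ± 0.21, cementoblasts 0.76 ± 0.05, SD, n = 3 each), although placement by 100 genes outside both lists, chosen on the other arrays, put 5 of 6 on their side and cementoblast replicate 3 on the osteoblast side of the midpoint. For cementoblast replicate 3 those genes were chosen with cementoblast replicates 1 and 2, which share epithelial and endothelial signal that it lacks. Its placement may reflect that signal and does not decide on a swap.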
